A study of Homo sapiens with 2 samples.

How the data were processed

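Gene expression was measured in SW780 cells, an established human bladder cancer cell line, on 2 one-colour (Cy3) Agilent microarrays with probes of 60 bases. Per the labels' protocols, 300000 cells were transfected with 100 pmol of either a pre-miR-137 molecule, a precursor mimic of the microRNA miR-137, or a negative control molecule with a lipid reagent, total RNA was taken after 48 h with TRIZOL, and 100 ng of it was labelled. The labels put 1 array in the control group and 1 in the miR-137 group, so each group has a single culture and a single hybridisation. Per the file headers, both arrays were on the same slide and came from the same scan, so neither differs between the groups.

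Per the file headers, the deposited processed signal is an intensity on a linear scale that Agilent Feature Extraction 10.7.3.1 (version 10.7 in the submitters' processing notes) made within each array by subtracting background and correcting spatial trends, with no scaling between arrays. The header gives hg19 as the build of the probe annotation. The deposited scanner files also hold the raw mean spot intensity, the median local background intensity and the intensity error of the software's own error model. A deposited table of the whole series holds 1 value per spot. Each of its values divided by the processed signal of the same spot lay between 0.995 and 1.005, so it is the same signal rounded; its median was 50.95 for the control array and 52.25 for the miR-137 array over all spots.

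Each array holds 62976 spots, of which 58717 are not controls and represent 42405 probes. Spots that the scanner software marked as outliers were left out, 309 on the control array and 450 on the miR-137 array; no non-control spot was saturated. The processed signal was taken to log2, the 75th percentile of the array was subtracted, and the spots of a probe were averaged. The 75th percentile was 670.7 on the control array and 607.3 on the miR-137 array. A probe was measured where more than 50% of its spots were well above background on both arrays by the software's flag, and a gene's value is the mean over its measured probes. Probes were named through the unversioned RefSeq accession in a table of the GRCh38.p14 assembly (24826 probes), else through a current symbol (1188) or a synonym held by a single gene (472); the other 15919 probes kept the name in the files. For a gene well above background on only one array, a level was set for the dim array. It was the higher of the gene's own value and the lowest level among probes well above background there. The difference is given as a lower bound, except where the gene's own dim value was the higher. That lowest level was −5.36 on the control and −4.91 on the miR-137 array, so at the same level a dim gene could pass on the control array alone.

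With 1 array per group there is no spread between samples, so no test of the difference was made, no p-value is given, and genes are counted by size alone, at 2-fold. The error within an array was taken from 697 probes with at least 8 kept spots on each array. Before the data were examined, 26 gene lists were fixed, together with the main settings, their alternatives and the rule for the genes to be named. For a list, the median log2 difference is given relative to the median of all measured genes, with a 95% interval from 1000 resamplings of its members, and with its percentile among the medians of 10000 random gene lists of the same size matched on mean expression in 20 bins. These percentiles describe these 2 arrays; genes are not replicates. Sites for miR-137 were searched in the probes' own sequences because no 3′ UTR sequences were used here: an 8mer (AGCAATAA), a 7mer-m8 (AGCAATA), a 7mer-A1 (GCAATAA) or only the 6 bases they share (a 6mer). The same search was made for 17 other microRNA families, leaving out probes with a miR-137 6mer, and all words of 7 bases held by at least 50 measured probes were ranked by their median difference after removing the median of their expression bin.

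The named genes are the 14 with the lowest and the 14 with the highest difference among measured genes with a symbol and a mean level at or above the lower quartile; up to 4 members per list that differed by at least 2-fold, or the first 2 by size where none did; every measured reported target that differed by at least 1.5-fold; and the 5 genes with the largest lower bound. The results of some of these genes and of 1 of the lists are not reported here. Genes added to complete a small count were chosen after their values were seen and are named as such.

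The alternatives were normexp background correction (limma 3.58.1 in R 4.3.3, offset 50), quantile, median or no scaling, no filter or a stricter filter on dim probes, the brightest probe or the median probe per gene, no saturated spots, the deposited value table, thresholds of 1.5-fold and 4-fold, random lists matched differently, and probes with exactly 1 site. Normexp started from the raw mean spot and median local background intensities, without the software's correction of spatial trends. After the data were seen, a further alternative was added that leaves out spots in patches of raised signal. A spot counts as lying in a patch where, among the other spots within 3 rows and 3 columns that were not well above background on the other array (at least 4 of them), at least 30% were well above it on this one. Computations were made in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. The steps were tested on simulated data made from the control array, with 200 genes moved by known folds among 20554. All 50 genes moved 3-fold and all 50 moved 4-fold passed the 2-fold threshold, as did 25 of 50 moved by exactly 2-fold. Of 50 moved 1.5-fold, 0 passed, and of the 20354 left as they were, 0 passed. The simulated noise was equally small for dim and bright spots, and the background flags were those of the control array. No brightness trend, patches or difference between cultures was added. The simulation therefore checks the steps and gives no rate of false calls for the real arrays.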

Results

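SW780 cells, a human bladder cancer line, were profiled 48 h after transfection with a miR-137 precursor (1 array) or a negative control molecule (1 array). The comparison asks which transcripts differ when the cells are given miR-137. MicroRNAs repress mRNAs that carry a short match to their seed; the mature miR-137 itself is not measured on this array, so its level could not be checked. Of the non-control spots, 63.4% were well above background on the control array and 61.8% on the miR-137 array. In all, 23642 probes and 19351 genes were measured on both arrays, 13352 of them with a gene symbol and 12672 protein-coding. Every difference below is the miR-137 array minus the control array on the log2 scale, from single cultures with no replicates, so no difference has been set against the spread between cultures.

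Repeated spots give the error within an array. Over 697 probes with at least 8 spots on each array, the median SD of the log2 difference was 0.097, from 0.178 in the dimmest 25% of these probes to 0.069 in the brightest 25%. Of 11690 pairs of spots of the same probe on the same array, 15 were at least 2-fold apart. For the named measured genes, the scanner software's own error of the log2 difference lay between 0.20 and 0.30. The median of all measured genes was 0.12 above 0 on this scale, and the median difference went from 0.33 in the dimmest of 10 brightness classes of probes to −0.04 in the brightest, so list and site medians are given relative to all genes or probes and beside lists matched on expression.

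By size, 558 genes were at least 2-fold lower in the miR-137 array and 738 at least 2-fold higher, so that 43.1% of them were lower. Counted relative to the median gene, 697 were lower and 501 higher (58.2% lower); with no scaling between the arrays the numbers were 727 and 478 (60.3%), with quantile normalization 651 and 540 (54.7%), and with normexp background correction 334 and 258 (56.4%). The balance between the 2 directions therefore depended on the scaling and the background correction. Among protein-coding genes, 493 were lower and 376 higher. Where several probes of a gene were measured, all had the same sign for 78 of the 78 lower and 90 of the 92 higher genes. These genes were selected by the mean of the same probes, which favours agreement in sign, so the agreement is no independent check.

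**Figure D1:**
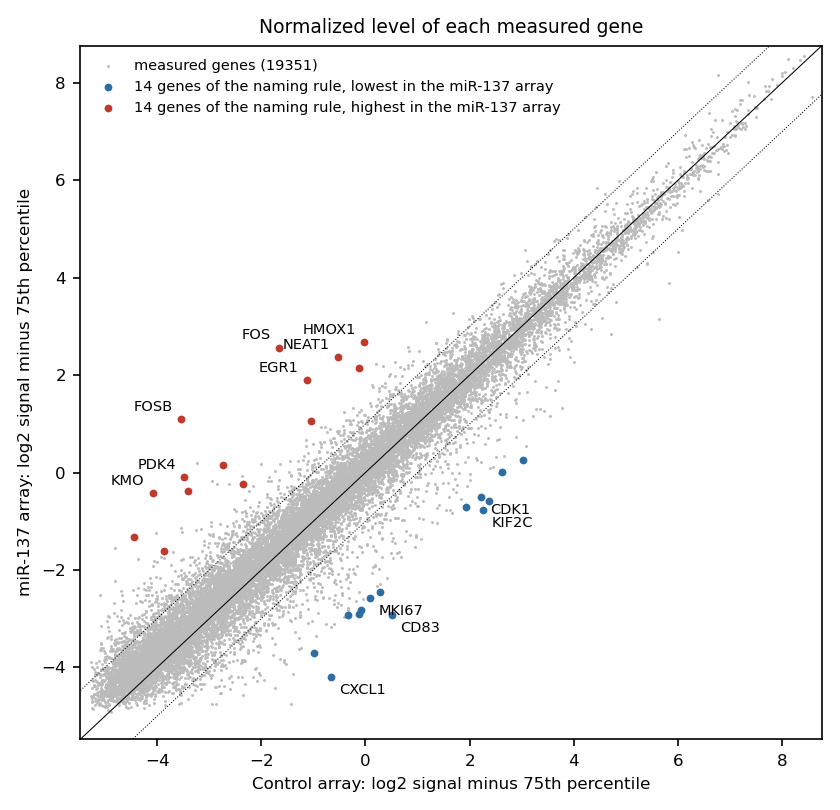
Normalized level (log2 signal minus the array's 75th percentile) of each of the 19351 measured genes on the control array (x axis) and the miR-137 array (y axis); the solid line marks equal levels and the dotted lines a 2-fold difference. The 14 genes of the naming rule with the lowest difference (blue) run from CXCL1 at −3.54 to NUF2 at −2.59, and the 14 with the highest (red) from PLA2G10 at 2.11 to FOSB at 4.63; KMO rests on a single spot in a patch of raised signal.

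Among the fixed lists, the cell cycle lists were furthest below the rest in the miR-137 array. All 25 genes of the G2/M and mitosis list were at least 2-fold lower, among them CDK1, the kinase that drives entry into mitosis (−2.74, 6.67-fold), the mitotic kinesin KIF20A (−2.73), the proliferation marker MKI67 (−2.68) and the mitotic kinase AURKB (−2.51). Of the 25 G1/S genes, 20 were at least 2-fold lower, including RRM2, a subunit of ribonucleotide reductase (−2.72), cyclin CCNE2 (−2.18), the transcription factor E2F2 (−2.04) and the replication factor GINS2 (4.01-fold). The other 5 G1/S genes, named after their values were seen, were CDK4 (−0.70), SLBP (−0.67), CDK2 (−0.64), CDC6 (−0.51) and CCND1 (0.03). Relative to all genes, the median was −2.38 for the G2/M list (95% interval −2.51 to −2.01) and −1.51 for the G1/S list (−1.92 to −1.28), both lower than every one of 10000 matched random lists (percentile 0). The mitotic kinesin KIF2C (−3.04), which is in neither list, was also among the 14 lowest genes, as were the kinetochore proteins SPC25 (−2.64, a single spot) and NUF2 (−2.59).

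Genes that earlier work reported as miR-137 targets were mostly lower. Of 26 measured, 25 lay below the median of all genes, and 6 were at least 2-fold lower and 0 higher. These 6 were CDK6, the G1 kinase (−1.81, signal 2323 on the control and 601.8 on the miR-137 array), the mitotic kinase AURKA (−1.44), the histone methyltransferase EZH2 (−1.29), the nuclear receptor ESRRA (−1.15), the transcription factor TCF4 (−1.08) and the glutamine transporter SLC1A5 (−1.06). MIB1 (−0.83), YBX1 (−0.79), the focal adhesion protein PXN (−0.73), CSE1L (−0.70) and CDC42 (−0.65) were at least 1.5-fold lower. The 3 probes of CDC42 disagreed, from −1.37 to 0.13. The exception above the median was MSI1 (0.55), named after its value was seen. The list's median was −0.54 relative to all genes (95% interval −0.87 to −0.39; percentile 0), and −0.50 over the 24 genes left without CDK6 and AURKA, which the cell cycle lists also hold (percentile 0). Only members of those lists were taken out, so the second median cannot separate targeting from the wider fall of cell cycle genes. On hg19, the CDK6 probe lies on chromosome 7 at 92234443 to 92234502 and the EZH2 probe on chromosome 7 at 148504505 to 148504564, both on the minus strand.

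Probes that hold a match to the miR-137 seed were, by their median, slightly lower than other probes. The median over 173 measured probes with a 7mer or 8mer site was −0.17 relative to all probes (95% interval −0.27 to −0.08), below all of 10000 probe lists matched on expression (percentile 0). By site, the median was −0.32 for 35 probes with an 8mer (percentile 0.01), −0.19 for 78 with a 7mer-A1 (0.09), −0.06 for 60 with a 7mer-m8 (9.1) and −0.10 for those with only a 6mer (2.71). Of the 173 probes, 64.7% lay below the median of all probes. Counted without subtracting that median, 11 were at least 2-fold lower and 10 at least 2-fold higher. Among probes with a gene symbol, the lowest belonged to the cohesin acetyltransferase ESCO2 (−2.53), SLC45A3 (−1.48), the lysosomal proteins GM2A (−1.41) and CTSF (−1.35), and EZH2 (−1.29), and the highest to STRA6 (1.95), all chosen after their values were seen. The EZH2 probe, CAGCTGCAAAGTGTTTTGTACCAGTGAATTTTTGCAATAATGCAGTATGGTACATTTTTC, holds a 7mer-A1. Among 17 other microRNA families, percentiles ran from 9.59 for the passenger strand miR-137-5p, with 14 probes, to 87.2 for miR-141/200a. Of 9946 words of 7 bases, GCAATAA had the 4th lowest median and AGCAATA the 52nd. A probe covers 60 bases of a transcript, so most genes with a site elsewhere count here as having none, and the site need not lie in a 3′ UTR. With no filter on dim probes the shift was −0.0368 (percentile 1.9).

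**Figure D2:**
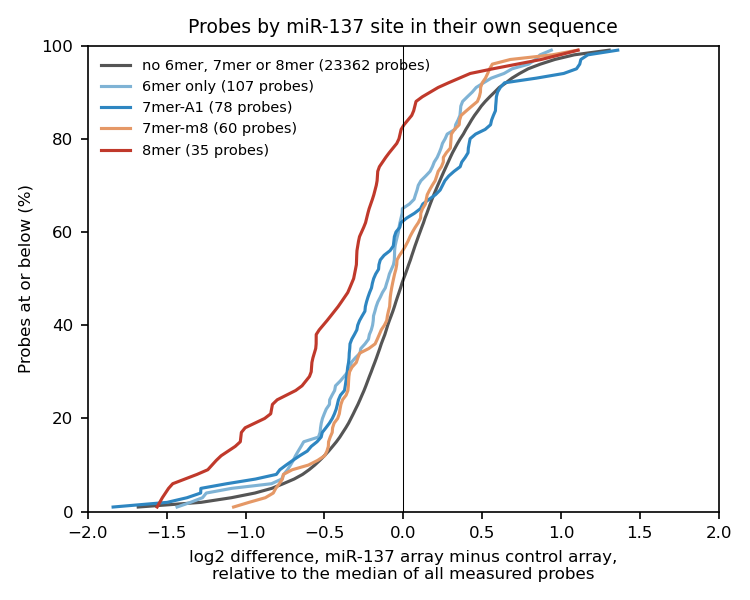
Share of measured probes (y axis, %) at or below each log2 difference relative to the median of all measured probes (x axis), from the 1st to the 99th percentile, for probes with an 8mer, 7mer-m8, 7mer-A1, only a 6mer or no miR-137 site in their own sequence. At the median, the 35 probes with an 8mer lie furthest to the left, at −0.32; near both ends the curves cross.

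Matrix, adhesion and inflammatory genes were also lower as groups. In the list of integrins and extracellular matrix, 3 of 23 measured genes were at least 2-fold lower and 0 higher, among them thrombospondin THBS1 (−1.21) and the collagen COL4A1 (−1.06). The median was −0.63 relative to all genes (95% interval −0.75 to −0.12; percentile 0). In the inflammatory and NF-kB list, 3 of 12 were at least 2-fold lower: the neutrophil chemokine CXCL1, which had the lowest difference of all named genes (−3.54, 11.6-fold), the ubiquitin-editing enzyme TNFAIP3 (−1.51) and BIRC3 (−1.17); the median was −0.47 (95% interval −0.96 to −0.18; percentile 0.08). A further 4 members of this list, CXCL8, CXCL2, TNF and CSF2, were well above background only on the control array, at least 5.08-fold higher there for CSF2, 3.02-fold for CXCL8, 1.63-fold for TNF and 1.30-fold for CXCL2; they were named after this was seen. CD83, a surface protein of activated immune cells, was also low (−3.43).

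Markers of urothelial state went in both directions. Of 12 measured basal genes, 2 were at least 2-fold lower, S100A2 (−1.47) among them, while the keratins KRT16 (2.04) and KRT14 (1.13) and, named after its value was seen, KRT17 (1.04) were at least 2-fold higher; these keratins have closely related copies, and cross-hybridisation was not excluded. The median of the basal list was −0.58 (percentile 0) with a 95% interval of −0.95 to 0.43, and 4 of its 12 measured genes are also in the matrix list. Well above background only on the control array were 3 more basal genes, named after this was seen, at least 2.52-fold higher there for COL17A1, 1.66-fold for KRT6A and 1.20-fold for DSC3. Of 20 luminal genes, KRT20, a keratin of umbrella cells, was lower (−2.78) and TRIM31 higher (1.31); the median was −0.11 (percentile 44.1). The epithelial list had a median of 0.05 (percentile 96.4), with 1 of 20 genes at least 2-fold higher, the transcription factor ELF3 (1.03). Among the 7 measured mesenchymal genes, N-cadherin CDH2 was lower (−1.07) and COL1A1 higher (1.25), and the median was −0.44 (95% interval −0.77 to 0.58; percentile 0.895). COL1A1 was dim, with a signal of 30.6 on the control and 66.1 on the miR-137 array, so its difference is uncertain. A further 4 mesenchymal genes, named after this was seen, were well above background only on the control array. LUM was at least 3.42-fold higher there and MMP2 at least 1.34-fold. For FAP (2.48-fold) and ZEB2 (1.17-fold) the gene's own dim value was used, so these are not lower bounds.

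Immediate early genes, which are induced within minutes by growth factors and stress, included the highest values. FOSB was 24.7-fold higher (4.63), FOS 18.7-fold (4.23) and EGR1 8.14-fold (3.03), each from 2 spots per array, and ATF3 was higher over 4 probes (1.42). DUSP1 (1.39) was the fifth of 15 measured genes at least 2-fold higher, and FOSL1 (−1.03) was the one at least 2-fold lower; both were named after their values were seen. The list's median was 0.37 relative to all genes (95% interval 0.00 to 1.26; percentile 99.96); over the 12 genes left without FOS, FOSB and EGR1, a list made after their values were seen, it was 0.14 (percentile 93.75). That list lacks the highest members while the matched lists kept theirs, so part of the drop in percentile was fixed in advance. The FOS probe lies on hg19 chromosome 14 at 75748214 to 75748273 and the FOSB probe on chromosome 19 at 45978205 to 45978264.

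Genes induced by p53 were slightly higher as a group, with a median of 0.16 (95% interval −0.01 to 0.41; percentile 98.7) and 3 of 20 at least 2-fold higher: the pro-apoptotic BBC3 (1.76), the stress cytokine GDF15 (1.40) and ZMAT3 (1.15). The unfolded protein and amino acid stress list had a median of 0.12 (95% interval −0.52 to 0.34; percentile 99.0) with 1 of 20 genes at least 2-fold higher, CHAC1 (1.01); with no filter on dim probes the medians of these lists were −0.00822 for p53 targets (percentile 98.9) and −0.0894 for the stress list (percentile 95.8). Among 22 apoptosis regulators, BMF (2.07) and BBC3 were at least 2-fold higher and 2 genes lower, BIRC3 among them, with a median of 0.05 (percentile 85.9). Of 22 interferon response genes, MX2 (2.11), IFIT2 (1.35) and RSAD2 (1.10) were at least 2-fold higher and IFI44 (−1.73) lower, with a median of 0.07 (percentile 80.3). A further 3, named after this was seen, were well above background only on the control array: IFI44L (at least 1.75-fold higher there), HERC5 (at least 1.54-fold) and IFITM1, for which no bound above 1 was reached.

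The other high values came from genes of varied function. They included PDK4, a kinase that restrains pyruvate oxidation (3.38), CDA, cytidine deaminase (3.02), the kinase DAPK2 (2.89), the nuclear noncoding RNA NEAT1 (2.91, a single spot) and HMOX1, haem oxygenase (2.70, 10 spots). ATG9B (3.12), CPZ (2.28) and DHRS9 (2.26) each rest on a single spot, while PLA2G10 (2.11) has 2. KMO stood at 3.65, but its only measured spot lies in a patch of raised signal on the miR-137 array, and its other probe read 4.07 on the control and 5.22 on the miR-137 array, not well above background on either. Among the low values were PPP1R3C, a glycogen-targeting phosphatase subunit (−2.73, a single spot), and the histone genes H3C15 (−2.95) and H3C2 (−2.61), whose near-identical copies make the gene uncertain. Well above background on only one array were 1194 genes (control) and 724 genes (miR-137). Of these, 100 (control) and 387 (miR-137) differed by at least 2-fold. The lowest level set for a dim gene was −5.36 on the control and −4.91 on the miR-137 array. A 2-fold difference was thus easier to reach for genes seen only on the miR-137 array. Spots in patches of raised signal were also kept, so these counts cannot be compared between the arrays. List members seen only on the control array are to be read beside its larger total. The largest lower bounds, all higher in the miR-137 array, were at least 48-fold for FFAR3, 33.6-fold for CNGA4, 25.7-fold for TTC29, 24.6-fold for ABI3BP and 20.2-fold for MYOC. The first 4 each rest on 1 spot in a patch of raised signal, and the other probes of FFAR3, TTC29 and ABI3BP were not well above background on either array; the 2 spots of MYOC lay apart and read 276.0 and 323.7.

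The remaining lists lay within the central 95% of matched random lists. In the TGF-beta list, INHBA (−1.26), TGFBR2 (−1.21) and, named after its value was seen, CCN1 (−1.10) were at least 2-fold lower and 2 genes higher, ID2 (1.16) among them, with a median of 0.02 (percentile 78.3). The Wnt list had a median of −0.09 (percentile 25.6), with RNF43 at −1.06, and the chromatin modifiers −0.09 (percentile 27.0), with EZH2 the 1 gene of 27 at least 2-fold lower. The glycolysis and hypoxia list stood at −0.20 (percentile 11.3), with NDRG1 at 1.10; CA9, named after this was seen, was well above background only on the control array, at least 4.98-fold higher there. In 7 lists no gene differed by 2-fold. These were cholesterol synthesis at −0.05 (percentile 64.5; MSMO1 0.54, HMGCS1 0.45), receptor tyrosine kinases and MAPK at −0.08 (32.6; ERBB3 0.68), small RNA machinery at −0.20 (5.04; PAN3 0.93, AGO4 −0.59), ribosomal proteins at −0.25 (7.81; RPL11 −0.65, RPS13 −0.62), housekeeping references at −0.17 (43.4; TFRC 0.50, HPRT1 −0.47), immune cell markers at −0.23 (5.33; CD3D −0.76, CD8A 0.54) and endothelial markers at −0.06 (26.0; VWF 0.63, ESAM 0.51).

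**Figure D3:**
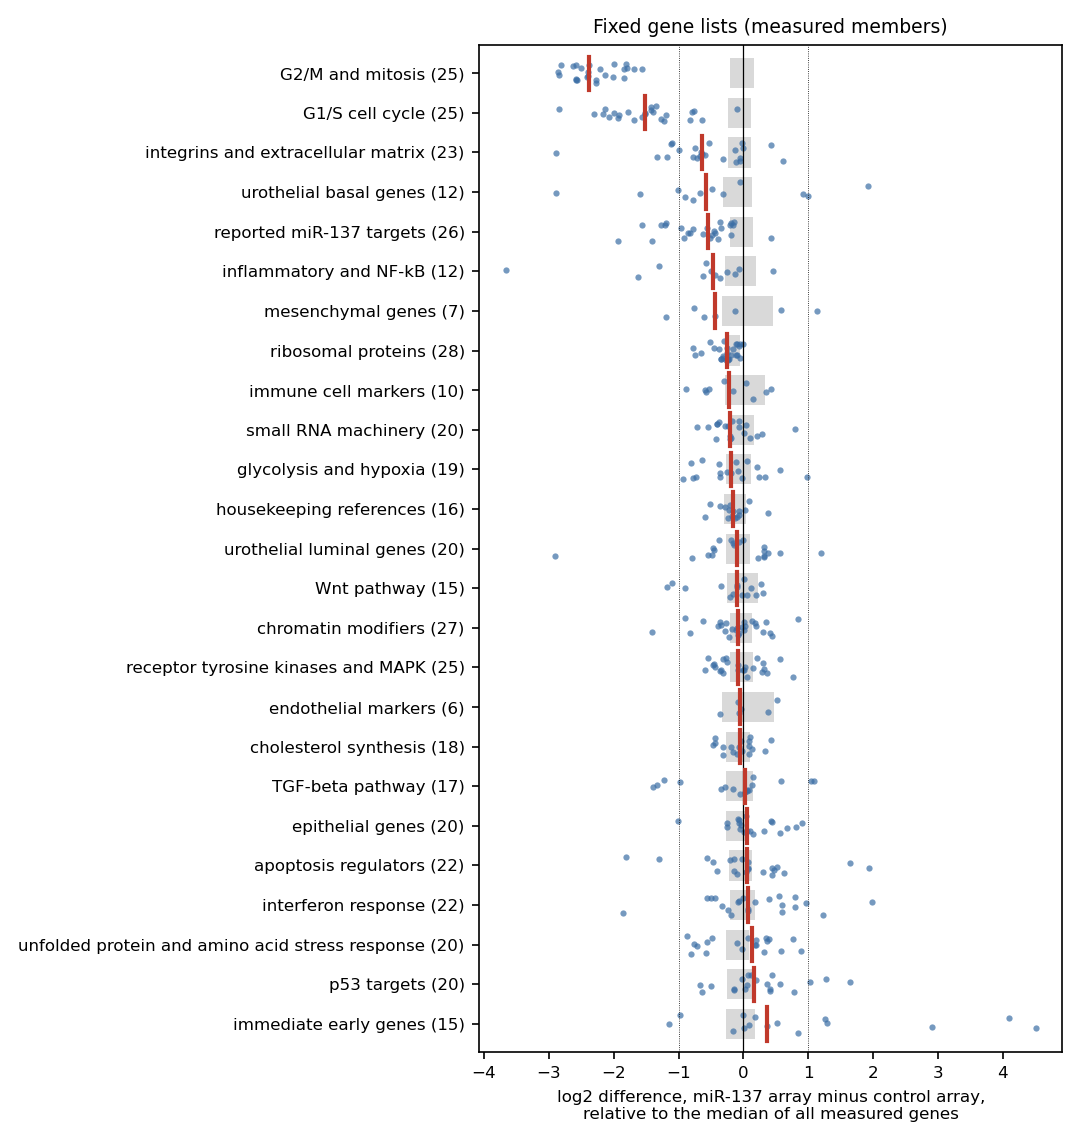
Log2 difference of each measured member (blue points) of 25 of the fixed gene lists (y axis, with the number measured) relative to the median of all measured genes (x axis), with the list's median (red line) and the central 95% of the medians of 10000 random lists matched on expression (grey band); dotted lines mark 1 above and below 0. The medians of the G2/M list (−2.38) and the G1/S list (−1.51) lie furthest from their bands.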

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

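No paired analysis was possible because each group has 1 array and no test was made; for the same reason no array could be left out. Over all alternatives, 0 of 893 comparisons of a named gene reversed a gene that differed by at least 2-fold, and 705 stayed within the SD of repeated spots (0.097); named genes at least 2-fold apart stayed so in 669 of 692 comparisons. Of 284 comparisons of a list's median, 271 lay within its 95% interval. Part of these could not have moved. Median scaling and no scaling shift all genes alike, while list medians are relative to all genes. No non-control spot was saturated and the deposited table is the same signal rounded, which holds for the comparisons of named genes too. The tallies therefore overstate how much was tried. The number of lists outside the central 95% of matched lists was 10 and ranged from 7 (stricter filter on dim probes) to 12 (quantile normalization). At the 2-fold threshold, the counts of genes depended on how dim probes were treated. With normexp, 334 genes were at least 2-fold lower and 258 higher. The spread of repeated spots was then 0.194, against 0.097 with the processed signal. This alternative also lacks the software's spatial correction, so it changes more than the treatment of dim probes. With no filter on dim probes, 1185 were lower and 2835 higher, the site shift was −0.0368, and the p53 list (−0.00822) and the unfolded protein and amino acid stress list (−0.0894) turned below 0 relative to all genes; among matched lists the first stayed outside the central 95% (percentile 98.9) and the second lay within it (95.8). With the stricter filter, which keeps 9689 genes, 237 were lower and 178 higher. With no scaling, 478 were higher. The threshold itself moved the counts to 1304 lower and 2744 higher at 1.5-fold and to 105 and 42 at 4-fold. Apart from the smaller number of genes under the stricter filter and the thresholds, the cause was not tested. Leaving out spots in patches of raised signal, chosen after the data were seen, gave 560 lower, of which 554 were the same genes, and 687 higher, all 687 the same genes, and a site shift of −0.17; KMO then had no value. Searches of the longest, shortest or every 3′ UTR, and matching on UTR length, were not run because no UTR sequences were used here, and 2 probes with more than 1 site were too few for a value. Of the spots, 36.6% on the control and 38.2% on the miR-137 array were not well above background, and differences there are bounds or rest on such a dim value.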

Other observations

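Of the tests reported here, those on scaling, brightness and the single culture, on words of 7 bases, and on ERK feedback genes were chosen after the results they measure were seen; so were the metallothionein, histone, heat shock, ERK feedback and further FOXO lists, the immediate early list without FOS, FOSB and EGR1, and the count of spots in patches.

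Metallothioneins, small proteins that bind zinc and copper, were lower in the miR-137 array almost as a family. Of 9 measured, 8 were at least 2-fold lower, from MT2A (−2.50) and MT1H (−2.38) to MT1X (−1.18), whose 2 probes disagreed (−1.97 and −0.38), and the exception was MT3 (0.42). The median was −2.43 relative to all genes, below all of 10000 lists matched on expression. The MT1 genes are near-identical copies, so the members may not be separate measurements; the family's median lay lower than the −1.96 of both cell cycle lists together.

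Replication-dependent histone genes, which are transcribed mostly in S phase, were also lower. Of 59 measured, 19 were at least 2-fold lower and 1 higher, H2AC25 (1.10), with a median of −0.95 relative to all genes and below all matched lists. Besides H3C15 and H3C2, the linker histone H1-5 (−2.58) and H2AC16 (−2.31) were among the lowest. Many of these genes have near-identical copies, so the values of single members are uncertain.

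Cell cycle genes were lower as a set, with 45 of 50 measured genes at least 2-fold lower. Scaling between the arrays was too small to account for this. The difference of their 75th percentiles was −0.143 on the log2 scale. The median of both lists was no higher than −1.81 under 4 scalings, no scaling included, an outcome that was not in doubt. A bias that follows brightness is argued against: the median relative to all genes was −1.96, while the lowest of 10000 matched lists reached −0.30. That repeats, for both lists together, the matched comparison already given for each, so it is no separate evidence. Slower growth or a lower density of the single miR-137 culture for another reason stays open and cannot be told apart from the transfected microRNA, because the design holds 1 culture per group. That miR-137 lowers proliferation in these cells is therefore a hypothesis, which a second pair of cultures could test.

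Probes with a miR-137 site were lower by a median of −0.17. AU content is argued against: among 10000 probe lists matched on expression and AU content the percentile was still 0. The site words overlap AATAAA, the signal for poly(A) addition, but the 91 site probes without it had a median of −0.18 (percentile 0.02), while 1586 probes with AATAAA and no miR-137 6mer stood at −0.01 (percentile 76.8). Nor did words of 7 bases in general do as much, since both site words were among the lowest 0.523% of 9946 words. The site words are not separate evidence, since the 35 probes with an 8mer hold both. The 60 probes with a 7mer-m8 stood at only −0.06 (percentile 9.1), less low than the −0.10 of probes with only a 6mer. Repression through the seed stays a hypothesis, which the 7mer-m8 probes on their own do not bear out. The passenger strand's site, at −0.17 over 14 probes (percentile 9.59), was too rare to be judged.

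Of the 15 immediate early genes, FOSB, FOS and EGR1 were far higher. The 12 left without them had a median of 0.14 relative to all genes (percentile 93.75), within the central 95% of matched lists. Taking out the highest members lowers the median by construction, and the matched lists kept theirs. That percentile therefore cannot tell whether the remaining genes were shifted. Heat or handling stress at harvest stays open: 10 heat shock genes had a median of 0.14 relative to all genes (percentile 98.25), with HSPA1A at 0.81 and HSPA1B, its near-identical copy, at 0.75, although 4 of the 10 lay below the median of all genes. Lasting higher ERK signalling is argued against, though only weakly, by 11 ERK feedback genes, with a median of −0.44 (percentile 0.15). DUSP6 stood at −0.85 and, in the other direction, ETV4 at 0.43 and SPRY4 at 0.41. Of the 11, 3 are also in the immediate early list and 4 in the fixed list of receptor tyrosine kinases and MAPK. The feedback list was made after the values of those lists were seen, so it is weak evidence. Immediate early genes are induced within minutes, so feedback genes at a single time cannot exclude brief ERK activation at harvest. A direct or indirect effect of miR-137 was not tested apart from these, and 1 culture per group could not separate it from handling.

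Some of the highest genes, such as PDK4 (3.38) and BMF (2.07), are known targets of FOXO transcription factors, which suggests as a hypothesis that a FOXO programme was higher. Among 11 further FOXO targets, the median was 0.20 relative to all genes, at percentile 95.9 of matched lists, which lies inside the central 95% and not below the 0.1 set as the bound against it, so it decides neither way. BCL6 (0.84), PIK3IP1 (0.84) and IRS2 (0.72) were the highest of them, and SESN1 (−0.03) the lowest.

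On the miR-137 array, 851 spots lay in patches of raised signal, 550 of them in the first 48 of 384 rows. Of the spots in these patches that were not well above background on the control array, 42.5% were well above it on the miR-137 array, against 4.29% elsewhere. The same search on the control array found 577 spots, with 9.22% against 8.96%. Of 190 spots at least 8-fold brighter on the miR-137 array before scaling, 89 lay in the patches. Without spots in patches, the largest lower bounds were at least 20.2-fold for MYOC, 12.6-fold for TSHZ3 and 12.4-fold for SPATA45 and MB. All of these were higher in the miR-137 array, while IL7R was at least 10.2-fold higher in the control array. TSHZ3 and SPATA45 each rest on a single spot. The 5920 measured genes that keep a name from the files had a median difference of 0.23, against 0.08 for protein-coding genes.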
